A study of Homo sapiens with 33 samples.

How the data were processed

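Single cells of human donor retina and of the choroid, the vascular and pigmented layer behind it, were profiled as 33 droplet libraries. Per the labels' protocols, the retina and the layer of pigment epithelium and choroid were dissected apart, dissociated with papain, counted with trypan blue and loaded on a 10x Genomics Chromium instrument, and no sorting or removal of rods is described. The labels place 32 libraries in 4 groups, macula retina (11), peripheral retina (11), macula choroid (5) and peripheral choroid (5), and 1 library of pooled, hashed tissues in no group. Replicate numbers are the specimen numbers in the labels, so that the same number in different groups is the same specimen.

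The files hold whole-number UMI counts (unique molecular identifiers, 1 per captured transcript molecule) per gene and cell barcode, deposited as filtered 10x matrices without cell type names. Per the file headers, the count matrices came from software versions 3.1.0 (replicates 1 to 4), 5.0.1 (replicate 5), 6.0.0 (replicates 6 to 11) and 6.1.2 (replicate 12), and per the submitters' processing notes the genome build was hg38. Replicates 1 to 4 list 33538 genes and the others 36601. The 32732 genes in both were used, less 97 left out because they lie on the Y chromosome or tell a donor's sex, which leaves 32635. The gene list and software version split the libraries into a batch of replicates 1 to 4 and a batch of replicates 6 to 12, and within-batch values are given beside the pooled ones. Coordinates come from a GENCODE annotation on hg38, which may not be the annotation the authors used.

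Barcodes with at least 200 genes and at most 20% mitochondrial UMIs were kept, 58.4 to 99.3% per library. Doublet scores followed the Scrublet algorithm, and in each library the highest scores were removed, at 0.8% per 1000 barcodes (1.24 to 14.1% of cells). All 248202 cells that passed the filters were clustered together with scanpy 1.11.5 (2000 variable genes, 40 principal components, 20 neighbours, Leiden resolution 1 with leidenalg 0.10.2), which gave 78 clusters. A cluster was called "X-like" when at least 3 of that class's fixed markers were detected in at least 10% of its cells and lay at least 1 log2 unit above the median cluster. It stayed unnamed when over 50% of its cells were doublets, when its 10 leading genes held more markers of another class, or when its cells were shallow and no marker led. Doublet-scored cells were left out of all sums and shares, and class names here are rebuilt from markers, not taken from the authors.

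Counts were summed per library and class, and sums of at least 20 cells were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM normalization, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Between tissues, the macula and peripheral sums of 1 specimen were added first, so that n counts specimens. Expression is given as CPM, counts scaled to library size, with the SD over sums, and fold changes with the SE of the fit. Class shares are percents of the cells in a library. They were tested two-sided by permutation of the libraries (100000 resamples in the retina, all 252 arrangements in the choroid and all 4368 between tissues), adjusted over the classes that reach 0.1% in a group. The 30 gene lists were tested with limma 3.58.1's camera on the same design, with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. These designs, lists, markers and filters were fixed before the data were examined.

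Genes named by the first rule had an adjusted p under 0.05, a mean of at least 20 CPM in a group, the same direction in at least 80% of specimens with both sums, and a mean CPM in the class of at least 0.2 of that in the class where it was highest. The last part leaves out free RNA, transcripts that leak from broken cells into every droplet. From these came the 10 highest and 10 lowest by fold. Up to 4 members of each fixed list were added by adjusted p alone, so some lie under 20 CPM, differ in direction between specimens or lie below the free-RNA rule, and the text gives a selection. Some genes that met the rule are not reported here. Clone names, immunoglobulin and T cell receptor segments were left out. Applying the same rule to the fit with specimen as a block was decided after the data were seen, and so was naming members of call sets of 9 or fewer that fall outside the rule.

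The specimen numbers pair the libraries. The deviations of same-numbered sums from their group means correlated over genes with r above 0.1 in every pair of every class, except 1 of the 2 pairs of endothelial sums between tissues (0.0604, beside 0.122). Paired fits, with specimen as an additive block, or sign flips within specimens for shares, are printed beside a result where they change its call.

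The edgeR tests, camera with the preset correlation and the unpaired share test were tested on simulated counts with known changes. DESeq2, camera with an estimated correlation and the sign-flip tests were not. Simulated genes were drawn independently, so the simulations do not show how camera behaves when genes correlate. For the test without a block, the simulated sums of a specimen were drawn independently, while the real ones are paired. Its recovery and false-call rates below may therefore not hold for the real sums. Of genes raised or lowered 4-fold, the test without a block recovered 87.9% for rods (13063 genes), 89.4% for cones (10614), 89.4% for bipolar cells (14822), 93.9% for Müller glia (14361), 84.8% for retinal phagocytes (5889), 42.4% for choroidal endothelium (7101), 36.4% for fibroblasts (9960), 69.7% for melanocytes (11361), 21.2% for choroidal phagocytes (7311), 83.3% for phagocytes between tissues (9080), 83.3% for endothelium between tissues (6626) and 9.09% for the interaction (9089). With the block 74.2 to 100% were recovered. False calls made up 0 to 27.9% of the calls without the block and 1.71 to 10.8% with it, and with the block they exceeded 5% in 10 of 12 comparisons, the highest being rods (18 of 167). A 4-fold change of a share was recovered in 99.0% of retinal, 3.5% of choroidal and 94.0% of tissue simulations. Each class there stood at 3% of 5000 cells in independent libraries, with an SD of 0.5 on the natural log scale. Real shares such as that of ganglion-like cells (1.45% ± 2.05 in the macula) spread more, and recovery at such a spread was not tested.

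Alternatives covered the specimen block, normalization (TMM against RLE), DESeq2 1.42.0, the filters on genes, cells and doublets, finer clusters, at least 50 cells per sum, genes above the free-RNA rule alone, shares among non-rod cells and as log2 odds, leaving out shallow libraries, and leaving out each choroid replicate. Leaving out retina replicate 7, because cluster 59 of the cones came mostly from it, and the barcodes shared in replicate 11 were added after the data were seen. P-values treat the specimens as independent, and the labels do not say whether 2 specimens came from 1 person. Exact intervals and floors cover counting error only.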

Results

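Single-cell libraries were made from the retina and the choroid of human donor eyes, each sampled in the macula, the central region that serves sharp vision, and in the periphery. The retina groups held 11 libraries each (replicates 1 to 4 and 6 to 12) and the choroid groups 5 each (replicates 1, 3, 4, 8 and 10). One further library, replicate 5, pooled hashed tissues and entered no comparison. Total UMI counts ran from 6816689 (replicate 1) to 73095677 (replicate 7) in macula retina, from 6245987 (replicate 1) to 74609385 (replicate 6) in peripheral retina, from 2480099 (replicate 1) to 46362234 (replicate 10) in macula choroid and from 1612498 (replicate 1) to 90218629 (replicate 10) in peripheral choroid. The ungrouped library held 75293063. Replicate 1 was shallow in all 4 groups, with a median of 514 to 669 UMIs per kept cell, against 2188 to 11178.5 elsewhere. The 248202 cells that passed the filters formed 78 clusters, which were named by fixed markers as rod-like, cone-like, bipolar-like and so on.

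Astrocyte-like and ganglion-like cells made up larger shares of macular than of peripheral retina, the first question the labels pose. Astrocyte-like cells, glia that express GFAP, averaged 1.88% ± 1.73 (SD, n = 11) of the cells of macular libraries and 0.293% ± 0.230 (SD, n = 11) of peripheral ones, a 6.40-fold difference seen in 10 of 11 specimens (permutation p = 0.00051, adjusted over 15 classes 0.00765). Ganglion-like cells, the neurons whose axons form the optic nerve, averaged 1.45% ± 2.05 in the macula and 0.0241% ± 0.0357 in the periphery and were higher in the macula in 10 of 11 specimens (permutation p = 0.0035, adjusted 0.0262). They numbered 1131 macular and 22 peripheral cells, too few in the periphery for a test of their genes. Rod-like cells, the photoreceptors of dim light, averaged 17.5% ± 16.2 in the macula and 30.6% ± 24.8 in the periphery, which did not pass (permutation p = 0.157, adjusted 0.556), although they were higher in the periphery in 9 of 11 specimens. With specimens paired, rods came close to the threshold but did not pass (sign-flip p = 0.0137, adjusted 0.0684). Bipolar-like cells, the interneurons behind the photoreceptors, averaged 42.4% ± 21.2 and 39.95% ± 26.8 in macula and periphery, and Müller-like cells, the radial glia of the retina, 28.6% ± 10.4 and 22.8% ± 10.98. Cone-like cells averaged 0.823% ± 1.12 and 1.14% ± 1.22, and phagocyte-like cells 3.51% ± 3.86 and 2.15% ± 2.03. None of these 4 classes passed (adjusted p from 0.556 to 0.869).

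Within replicates 6 to 12, astrocyte-like cells averaged 2.54% in the macula and 0.307% in the periphery (exact permutation p = 0.000583), ganglion-like cells 2.25% and 0.0379% (p = 0.00583) and rod-like cells 26.4% and 45.9% (p = 0.0309). Within replicates 1 to 4 the same classes averaged 0.716% and 0.269% (exact permutation p = 0.371), 0.0518% and 0% (p = 0.143), and 1.85% and 3.67% (p = 0.629). Ganglion-like cells were 0 of 25354 peripheral cells there, which allows a share of up to 0.0118%. The macular excess of ganglion-like cells no longer passed as a share of non-rod cells, where it stood at 2.04% ± 2.83 against 0.0579% ± 0.0997 (permutation p = 0.0156, adjusted p = 0.109), or without retina replicate 7 (0.0632).

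**Figure D1:**
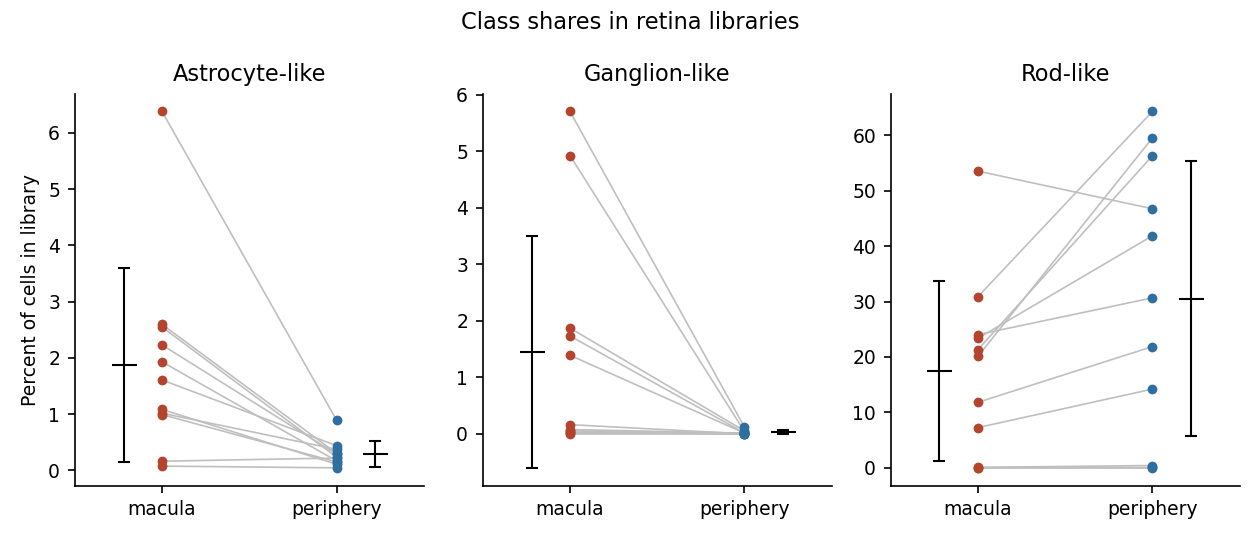
Percent of cells per retina library (y axis) in the macula and the periphery (x axis) for astrocyte-like, ganglion-like and rod-like cells; lines join the 2 libraries of a specimen, and the black marks are the mean ± SD of 11 libraries. Astrocyte-like cells averaged 1.88% and 0.293%, and ganglion-like cells 1.45% and 0.0241%.

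Müller-like cells differed in 1657 of 14547 genes between the regions of the retina. PMP2 (ENSG00000147588, chromosome 8, 81440326 to 81447523, minus strand), which encodes a lipid-binding protein of myelin, stood at 83.1 ± 69.5 CPM (SD, n = 11) in the macula and 0.0280 ± 0.0781 CPM (SD, n = 11) in the periphery. Its 10114 against 5 UMIs gave a log2 fold change of 10.28 ± 0.61 (SE, edgeR adjusted p = 7.44e-11). LHX9 (ENSG00000143355, chromosome 1, 197911902 to 197935478, plus strand), a LIM homeobox transcription factor, went the other way, from 45.1 ± 28.3 CPM in the periphery to 0.240 ± 0.290 CPM in the macula (log2 fold −7.32 ± 0.50, edgeR adjusted p = 7.98e-10). Enzymes of retinoic acid breakdown changed in opposite directions. CYP26A1 (ENSG00000095596, chromosome 10, 93073475 to 93077890, plus strand) rose 6.33-fold in the macula (65.2 ± 81.8 against 10.7 ± 13.3 CPM, edgeR adjusted p = 0.0109). CYP26B1 (ENSG00000003137, chromosome 2, 72129238 to 72148038, minus strand) was 21.8-fold higher in the periphery (15.7 ± 21.0 against 0.652 ± 0.683 CPM, adjusted p = 1.08e-05). DIO2 (ENSG00000211448, chromosome 14, 80197527 to 80387757, minus strand), which activates thyroid hormone, rose 3.49-fold in the macula, from 104 ± 39.2 to 369 ± 152 CPM (adjusted p = 1.84e-05). DIO3 (ENSG00000197406, chromosome 14, 101561351 to 101563452, plus strand), which inactivates it, was 10.2-fold higher in the periphery (13.3 ± 8.995 against 1.20 ± 1.66 CPM, adjusted p = 0.000263). All 6 genes kept these directions in 11 of 11 specimens.

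Of 18 measured genes of the retinoic acid and thyroid hormone list, 3 rose and 6 fell in macular Müller-like cells (3 and 7 adjusted over the list alone), and the list as a whole did not move one way (camera adjusted p = 0.301). DHRS3, which reduces retinal to retinol, was 4.07-fold higher in the periphery. DKK1, which encodes a secreted protein, was 13.6-fold and SFRP2 30.6-fold higher in the periphery, and SFRP1 was 5.48-fold higher in the macula. Of 18 genes of collagens and matrix, 2 rose and 4 fell (2 and 5 over the list alone). The basement membrane collagen gene COL4A3 rose 5.198-fold, at 593 ± 241 against 110 ± 90.2 CPM, and SPARC, below the free-RNA rule, was 9.67-fold higher in the periphery. Of 16 loci tied to age-related macular degeneration, 3 rose and 2 fell (3 and 3 over the list alone). HTRA1, a secreted serine protease gene below the free-RNA rule, rose 2.51-fold, from 128 ± 53.5 to 328 ± 139 CPM (edgeR adjusted p = 0.00459). MFSD2A, a lipid transporter of the blood-retina barrier list, rose 3.81-fold, IL33, an alarmin cytokine, 6.17-fold, and the VEGF receptor gene KDR 1.87-fold. Of 13 glial reactivity genes, 1 rose and 2 fell, and the intermediate filament gene NES, below the free-RNA rule, was 5.75-fold higher in the periphery.

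All 13 mitochondrially encoded genes fell in macular Müller-like cells, over all genes and over the list alone, with a median log2 fold of −1.29 (camera adjusted p = 1.55e-16, and adjusted p = 0.0296 with an estimated correlation). MT-ND4, a subunit of respiratory complex I, stood at 3133 ± 735 CPM in the macula and 7456 ± 2193 CPM in the periphery (log2 fold −1.27 ± 0.21, edgeR adjusted p = 0.000241, n = 11 and 11). In the fit with specimen as a block all 13 fell again, and the list did not pass with an estimated correlation (adjusted p = 0.279). Of 30 ribosomal protein genes 17 fell, and all 30 over the list alone, with a median log2 fold of −1.10 (camera adjusted p = 2.96e-13, but adjusted p = 0.793 with an estimated correlation). Beside these lists, the 19 measured rod phototransduction genes, all free RNA here by the rule, had a median log2 fold of −0.996, with 0 called and 0 above the free-RNA rule (camera adjusted p = 0.00629, adjusted p = 0.793 with an estimated correlation). The 45 nuclear genes of oxidative phosphorylation had a median of −0.47, with 0 called by edgeR (camera adjusted p = 0.00023, adjusted p = 0.793 with an estimated correlation).

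Of the 1657 genes of Müller-like cells, 814 were higher in the macula and 843 in the periphery (24753 and 20835 cells, edgeR, n = 11 and 11), and 1069 lay above the free-RNA rule. The blocked fit called 6489, 3250 and 3239, of which 1656 were shared with the unpaired test. Without the shallow replicate 1 the unpaired count was 3173. Replicates 1 to 4 alone called 12 genes and replicates 6 to 12 alone 2418. Of the pooled calls measured there, 1546 of 1546 and 1655 of 1655 kept their direction. Each batch is a part of the pooled libraries that gave these calls. A shared direction, here and in the classes below, is therefore not independent support. Macular Müller-like cells lay mostly in clusters 6 (30.1%), 9 (27.2%) and 3 (16.4%), and peripheral ones in clusters 3 (34.7%), 11 (28.5%) and 17 (10.7%).

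**Figure D2:**
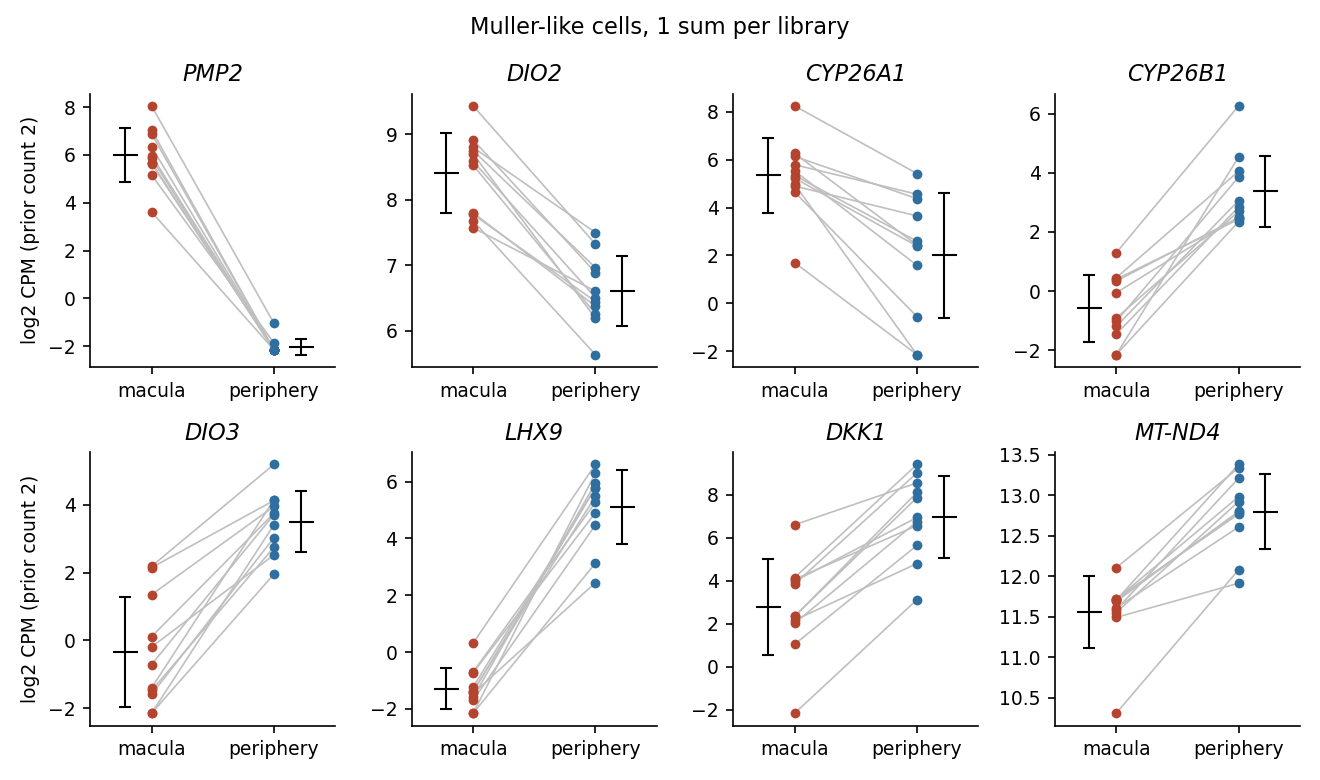
Expression of 8 genes in Müller-like cells as log2 CPM with a prior count of 2 (y axis) in the macula and the periphery (x axis); each point is the sum of 1 library, lines join a specimen, and the marks are the mean ± SD of 11 libraries. PMP2 stood at 83.1 and 0.0280 CPM on the linear scale and LHX9 at 0.240 and 45.1 CPM.

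**Figure D3:**
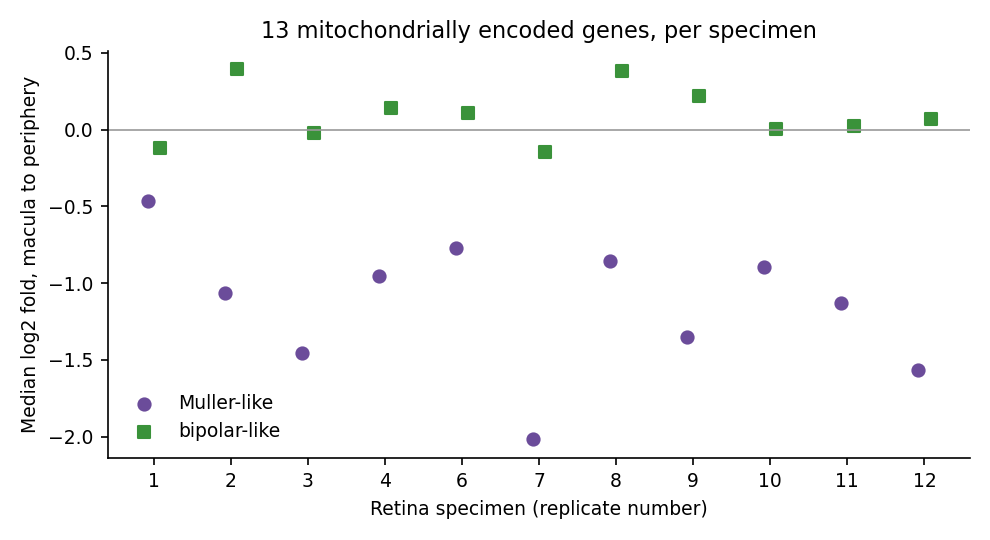
Median log2 fold, macula to periphery, of the 13 mitochondrially encoded genes (y axis) in each retina specimen by replicate number (x axis); purple circles are Müller-like and green squares bipolar-like cells. All 11 Müller-like points lie below 0, and the means over the 11 specimens were −1.14 and 0.0957.

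Bipolar-like cells of the macula held more RELN (ENSG00000189056, chromosome 7, 103471784 to 103989516, minus strand), the gene of the extracellular matrix protein reelin, at 53.9 ± 14.6 against 21.9 ± 10.4 CPM (SD, n = 11 and 11), a 2.46-fold rise (log2 fold 1.30 ± 0.21, edgeR adjusted p = 0.00461). The potassium channel gene KCNA1 rose 2.48-fold (adjusted p = 0.00373) and ADGRB3, an adhesion receptor of synapses, 1.60-fold (adjusted p = 0.0169). FGF11 (ENSG00000161958, chromosome 17, 7438273 to 7444937, plus strand), an intracellular fibroblast growth factor, was 3.82-fold higher in the periphery (27.2 ± 17.4 against 7.05 ± 4.67 CPM, log2 fold −1.93 ± 0.39, adjusted p = 0.0175), and PFKP, a phosphofructokinase of glycolysis, 2.20-fold (adjusted p = 0.0429). HS3ST4, SYN2 and the nuclear corepressor gene HR rose 1.84-, 1.64- and 2.45-fold, and CRABP2, which binds retinoic acid, was 2.69-fold higher in the periphery. Without retina replicate 7 these 4 did not pass (adjusted p = 0.0949, 0.062, 0.0914 and 0.0724). With bipolar clusters weighted alike in both regions, the mean log2 fold over specimens went from 1.36 to 0.46 for RELN, 1.30 to 0.25 for KCNA1, 0.69 to 0.29 for ADGRB3 and 0.72 to 0.24 for SYN2. HS3ST4 turned direction, from 0.89 to −0.09.

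Of 21 glycolysis genes 1 fell in macular bipolar-like cells, and 4 over the list alone. The list had a median log2 fold of −0.47 (camera adjusted p = 2.59e-14, but adjusted p = 0.506 with an estimated correlation). In the blocked fit 17 of the 21 fell (camera adjusted p = 4.59e-36, and adjusted p = 0.00567 with an estimated correlation), among them HK2 (log2 fold −1.93 ± 0.15) and ENO1 (−0.76 ± 0.07, below the free-RNA rule). The 19 rod phototransduction genes, all free RNA here by the rule, had a median of −0.68 with 0 called by edgeR (camera adjusted p = 0.000773, adjusted p = 0.749 with an estimated correlation). In all, 57 of 15041 genes differed (34 higher in the macula and 23 in the periphery, 39555 and 32030 cells), of which 21 lay above the free-RNA rule. The blocked fit called 1570, 749 and 821, of which 57 were shared. Replicates 1 to 4 alone called 0 and replicates 6 to 12 alone 19, with 57 of 57 and 54 of 54 pooled calls in the same direction. Macular cells lay mostly in clusters 1 (20.4%), 5 (17.5%) and 4 (14.8%) and peripheral cells in 1 (25.8%), 4 (16.9%) and 5 (10.96%).

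Cone-like cells of the macula held the long noncoding RNA PCAT4 (ENSG00000251321, chromosome 4, 79827471 to 79877770, plus strand) at 464 ± 169 CPM (SD, n = 5), against 9.29 ± 8.92 CPM (SD, n = 7) in the periphery. The log2 fold was 5.68 ± 0.57 (edgeR adjusted p = 6.83e-05). GPATCH1 rose 4.59-fold (121 ± 25.4 against 25.7 ± 11.8 CPM, adjusted p = 0.000239). VTN, the complement-regulating protein vitronectin, rose 4.09-fold (adjusted p = 0.019). SBK1, a kinase gene, was 4.54-fold higher in the periphery (adjusted p = 0.0103) and the transcription factor gene ZNF536 2.78-fold (adjusted p = 0.0245). RPE65, the isomerase of the visual cycle, was the called gene of that list's 11 measured members, at 26.3 ± 17.98 against 2.06 ± 3.81 CPM (adjusted p = 0.0499). It did not pass without retina replicate 7 (0.465). NRG1 and CLTB were 4.91- and 3.27-fold higher in the periphery and did not pass without that replicate either (0.149 and 0.14).

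The 16 immediate early genes had a median log2 fold of −0.60 in cone-like cells with 0 called by edgeR (camera adjusted p = 0.000114, adjusted p = 0.479 with an estimated correlation). In all, 43 of 10862 genes differed (17 higher in the macula and 26 in the periphery), and in the blocked fit 141, 61 and 80, of which 36 were shared. Of the 43, 25 lay above the free-RNA rule. All sums came from replicates 6 to 12, since no library of replicates 1 to 4 held 20 cone-like cells. Macular cones lay in cluster 36 (100%) and peripheral ones in clusters 36 (64.1%) and 59 (35.9%). Cluster 59 came almost wholly from peripheral retina replicate 7, and without the 2 libraries of that replicate 28 genes were called.

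Rod-like cells held PRL (ENSG00000172179, chromosome 6, 22287244 to 22297501, minus strand), the prolactin gene, at 26.0 ± 21.7 CPM in the macula (SD, n = 8) and 120.5 ± 79.6 CPM in the periphery (SD, n = 9). Its log2 fold in the blocked fit was −2.52 ± 0.21 (edgeR adjusted p = 2.83e-05), and without the block it did not pass (adjusted p = 0.169). In the blocked fit CEP170B (1.67 ± 0.13), PCAT4 (1.34 ± 0.21) and the ephrin receptor gene EPHA3 (0.94 ± 0.09) rose in the macula, and the phototransduction genes SAG (−0.39 ± 0.10) and GNGT1 (−0.52 ± 0.12) fell. It lowered 27 of 45 oxidative phosphorylation genes in the macula, among them COX4I1 (−0.55 ± 0.09), and 26 of 30 ribosomal protein genes. Both lists passed camera (adjusted p = 2.12e-34 and 2.06e-34, but adjusted p = 0.193 for both with an estimated correlation). Without the block edgeR called 0 members of these lists, with medians of −0.47 and −0.43 (camera adjusted p = 2.04e-14 and 1.62e-09, but adjusted p = 0.768 for both with an estimated correlation).

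The unpaired test called 9 of 13262 genes in rod-like cells, 2 higher in the macula and 7 in the periphery. None met the naming rule, since each lay below the free-RNA rule, and they are named here after their values were seen. NRN1 (log2 fold 3.62 ± 0.54) and ARHGAP32 (1.498 ± 0.24) were higher in the macula, and the zinc finger genes ZIC1 (−3.39 ± 0.41) and ZIC4 (−2.29 ± 0.37), BMP4 (−3.26 ± 0.51), NRG1, PLXDC1, DSCR8 and RGS3 in the periphery. The blocked fit called 476 genes, 138 and 338, including these 9. Without the shallow replicate 1 the unpaired test called 17. Replicates 6 to 12 alone called 13, with 9 of 9 in the same direction, and replicates 1 to 4 held too few rod sums, 1 and 2, for a test. Macular rods lay mostly in clusters 2 (50.3%) and 0 (42.4%) and peripheral ones in 0 (49.8%), 2 (25.2%) and 10 (21.7%), the last almost wholly from peripheral retina replicate 7.

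Phagocyte-like cells of the retina, which include microglia, held CX3CR1, a microglial chemokine receptor, at 79.1 ± 65.0 CPM in the macula and 42.8 ± 40.03 CPM in the periphery (SD, n = 10 and 10), higher in the macula in 10 of 10 specimens. LYVE1, a marker of perivascular macrophages, stood at 23.2 ± 49.5 and 52.3 ± 49.6 CPM, higher in the periphery in 10 of 10. Its macular mean rests on replicate 11, at 162.6 CPM, while the other 9 lay at 3.43 to 27.2 CPM. The unpaired edgeR test called 0 of 6074 genes (172 at an unadjusted p under 0.05), and DESeq2 called 4. These were LYVE1 (log2 fold −2.52) and the neuronal genes NEFL (3.86), SNCG (3.50) and PVALB (2.82), which lay below the free-RNA rule and are named after their values were seen. In the blocked fit edgeR called 56, 13 higher in the macula and 43 in the periphery. CX3CR1 (0.87 ± 0.16, adjusted p = 0.00849), the heat shock genes HSPA6 (1.29 ± 0.19) and HSPB1 (0.91) and CPVL (0.999) were higher in the macula. Higher in the periphery were LYVE1 (−1.76 ± 0.30, adjusted p = 0.00669), F13A1 (−0.87), EGR2 (−1.12) and EGLN3 (−1.34). Of 8 tissue macrophage genes the blocked fit lowered 2 in the macula (camera adjusted p = 1.38e-05, and adjusted p = 0.0206 with an estimated correlation). The unpaired fit called 0 of them (camera adjusted p = 0.0182, adjusted p = 0.768 with an estimated correlation). Of 16 heat shock genes the blocked fit raised 3, while the unpaired fit called 0 (camera adjusted p = 0.000535, adjusted p = 0.768 with an estimated correlation). Cluster 19 held 63.6% of macular and 65.8% of peripheral phagocytes and cluster 40 33.9% and 30.4%, and each batch alone called 0 genes.

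In the choroid no class passed as different in share between macula and periphery (0 of 11 by the exact permutation test and 0 at an unadjusted p under 0.05). That test recovered a 4-fold change in 3.5% of choroidal simulations, so the lack of calls does not show equal shares. With specimens paired, 5 differences cannot give an exact p below 0.0625, the value of endothelial-like and Schwann-like cells, both higher in the macula in 5 of 5 specimens. Natural killer and T cell-like cells averaged 31.1% ± 22.2 and 27.2% ± 25.5 (SD, n = 5 and 5), melanocyte-like cells 12.7% ± 18.4 and 23.5% ± 29.1 and fibroblast-like cells 16.8% ± 13.6 and 22.4% ± 30.1. Endothelial-like cells averaged 4.16% ± 4.20 and 2.10% ± 1.37 (exact permutation p = 0.405, adjusted 0.849) and Schwann-like cells 7.08% ± 10.4 and 4.70% ± 6.55 (p = 0.579, adjusted 0.849). The smallest p was that of erythrocyte-like cells, 0.373% ± 0.135 and 0.150% ± 0.148 (exact permutation p = 0.0635, adjusted 0.698). Within a batch, 3 against 3 libraries cannot give an exact p below 0.1, nor 2 against 2 below 0.333. Unnamed cells took 61.3% of macula choroid replicate 8, nearly all of them cluster 30, which mixed phagocyte and endothelial markers.

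Choroidal endothelial-like cells were higher in the macula for CA4, the carbonic anhydrase gene of the choriocapillaris (log2 fold 1.51 ± 0.29, edgeR adjusted p = 0.0188, higher in 3 of 4 specimens and lower in replicate 1), CXCL12 (1.13), FCN3 (1.85) and CRHBP (2.01 ± 0.40, adjusted p = 0.0207), all with specimen as a block over 4 pairs. In the same fit IL1R1, the interleukin 1 receptor (−2.41 ± 0.26, adjusted p = 0.000137), CYP1B1 (−1.60), the chemokine gene CCL2 (−1.44), ANGPT2 (−1.07) and the adhesion gene VCAM1 (−0.97) were higher in the periphery. The blocked fit raised 2 of 7 choriocapillaris genes and lowered 2 of 8 vein genes in the macula (camera adjusted p = 3.25e-10 for both, but adjusted p = 0.227 for both with an estimated correlation). Without the block edgeR called 0 of 7435 genes (54 at an unadjusted p under 0.05, 0 by DESeq2, n = 4 and 4), against 36 with it, 13 and 23. The unpaired camera test gave adjusted p = 0.0135 for choriocapillaris and 0.000898 for vein genes. With an estimated correlation these were adjusted p = 0.598 and adjusted p = 0.491. Cluster 39 held the class in both groups, and each batch alone called 0 genes.

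Fibroblast-like cells of the choroid held TFPI2, a protease inhibitor of the matrix (chromosome 7, 93885396 to 93890991, minus strand), at 13.5 ± 6.20 CPM in the macula and 111 ± 54.1 CPM in the periphery (SD, n = 5 and 5). Its log2 fold was −3.02 ± 0.40 (edgeR adjusted p = 0.0257). The transcription factor gene TBX15, named after its values were seen, stood at 11.6 ± 3.45 and 0.853 ± 0.589 CPM (log2 fold 3.52 ± 0.47, adjusted p = 0.0257). These were the 2 genes called of 10283, and the count ran from 0 (without choroid replicate 3, 4 or 8) to 7 (without replicate 10). TFPI2 did not pass without replicate 3, 4 or 8, nor TBX15 without any 1 of the 5. The blocked fit called 404 genes. In the macula 161 were higher, such as EPHA3 (2.41) and the basement membrane collagens COL4A1 (0.91) and COL18A1 (1.01). Mural-like cells averaged 0.0248% of the choroid here but a larger share with finer clusters. Other classes or unnamed clusters may therefore hold mural cells, and whether the fibroblast-like class does was not tested. In the periphery 243 were higher, such as SMOC2 (−3.19 ± 0.36, adjusted p = 0.00081), PI16 (−2.84) and RDH10 (−1.60). The blocked fit lowered 7 of 15 complement genes in the macula, among them C3 (−1.45), SERPING1 (−1.09) and CFD (−1.12). It lowered 7 and raised 1 of 16 retinoic acid and thyroid hormone genes. Both lists lay lower in the macula without the block too, with 0 called (camera adjusted p = 1.15e-06 and 0.000139, but adjusted p = 0.291 for both with an estimated correlation). Macular fibroblasts lay in clusters 25 (43.5%), 23 (38.1%) and 38 (18.4%) and peripheral ones in 25 (52.2%), 23 (27.4%) and 38 (20.4%). Each batch alone called 0 genes, with 2 of 2 in the same direction.

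Melanocyte-like cells of the choroid, all in cluster 8, had higher ARHGAP6 (log2 fold 2.96) in the macula, with specimen as a block over 3 pairs. DCT, a melanin synthesis enzyme (−1.44 ± 0.20, edgeR adjusted p = 6.09e-10), and CCND1 (−1.32) were higher in the periphery. The 3 pairs of DCT stood at 70.8 against 704, 148 against 246 and 1080 against 3234 CPM, macula against periphery. With 2 residual degrees of freedom, the fit took the spread from all genes together. The SE and p of DCT therefore do not measure its own spread between specimens. That fit called 259 genes, 96 and 163. The unpaired edgeR test called 0 of 11541 (218 at an unadjusted p under 0.05, 0 by DESeq2, n = 4 and 4) and 2 and 3 without choroid replicates 3 and 8. The 45 oxidative phosphorylation genes had an unpaired median log2 fold of −0.61 (0 called, camera adjusted p = 1.84e-08, but adjusted p = 0.654 with an estimated correlation). Choroidal phagocyte-like cells, in clusters 26 (70.3% and 83.4%) and 53 (27.8% and 14.8%), gave 0 calls of 7567 genes (23 at an unadjusted p under 0.05, 0 by edgeR and 0 by DESeq2, n = 4 and 5). The block called 4, named after their values were seen. SLC2A5, a fructose transporter gene of microglia, was lower in the macula (−1.54 ± 0.24, adjusted p = 0.0156). TYRP1 (−1.89), RGS5 (2.05) and TAGLN (1.997) lay below the free-RNA rule. Their 10 MHC class II genes had a median of −0.59 (0 called, camera adjusted p = 1.19e-05, but adjusted p = 0.793 with an estimated correlation). Each batch alone called 0 genes in both classes.

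Between the tissues, 16 of 18 classes differed in share. The choroid held more natural killer and T cell-like (29.2% ± 23.5 against 0.205% ± 0.571, SD, n = 5 and 11 specimens), fibroblast-like (19.6% ± 21.8 against 0.126% ± 0.228) and melanocyte-like cells (18.1% ± 20.8 against 0.199% ± 0.601). It also held more B and plasma cell-like (7.45% ± 7.85 against 0.0102% ± 0.0195) and endothelial-like cells (3.13% ± 2.70 against 0.194% ± 0.173). The retina held more bipolar-like (41.2% ± 23.1 against 0.0355% ± 0.0742), Müller-like (25.7% ± 9.69 against 0.0557% ± 0.114) and rod-like cells (24.0% ± 19.3 against 0.115% ± 0.166), each in 5 of 5 specimens with both tissues. Adjusted exact permutation p-values of these 8 ran from 0.000824 to 0.0276. With specimens paired, 5 differences cannot give an exact p below 0.0625, and 0 of 18 classes passed (adjusted p = 0.0804 at the lowest). Phagocyte-like cells, at 7.66% ± 4.57 and 2.83% ± 2.90, passed (exact permutation, adjusted p = 0.0291) but not without choroid replicate 1 (0.0527), 3 (0.103) or 10 (0.0527). Of the 5 specimens with both tissues, 3 held a larger phagocyte share in the choroid and 2 in the retina. Amacrine-like (0.472% ± 0.494 of the retina) and mural-like cells (0.298% ± 0.285), with an adjusted p of 0.0466 each, did not pass without any 1 of the 5 choroid replicates. With finer clusters mural-like cells turned direction, higher in the choroid by 5.31 percentage points (exact permutation, adjusted p = 0.00177). Within replicates 1 to 4, natural killer and T cell-like cells averaged 41.1% of the choroid and 0.0211% of the retina (exact permutation p = 0.0286). Within replicates 6 to 12 they averaged 11.2% and 0.311% (exact permutation p = 0.0278), and both p-values are the smallest the arrangements allow. Rods averaged 0.179% and 2.76% in the first batch (exact permutation p = 0.857) and 0.0177% and 36.2% in the second (p = 0.0278).

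Phagocyte-like cells of the choroid and the retina differed in 1987 of 9373 genes. CD209 (ENSG00000090659, chromosome 19, 7739994 to 7747564, minus strand), a lectin of macrophages and dendritic cells, stood at 192 ± 181 CPM in the choroid (SD, n = 5) and 1.97 ± 1.55 CPM in the retina (SD, n = 10). Its log2 fold was 6.75 ± 0.58 (edgeR adjusted p = 1.06e-06). SPP1 (ENSG00000118785, chromosome 4, 87975650 to 87983426, plus strand), the gene of osteopontin, was 105.8-fold higher in the retina (adjusted p = 0.000121). Of 10 tissue macrophage genes 9 rose in the choroid (10 over the list alone). MRC1, the mannose receptor, stood at 806 ± 486 against 45.1 ± 37.5 CPM (adjusted p = 5.08e-05), beside SIGLEC1 (44.1-fold), SELENOP (21.8-fold) and STAB1 (14.7-fold). Of 10 homeostatic microglia genes 6 fell in the choroid (7 over the list alone). TREM2, a lipid-sensing receptor, was 14.3-fold higher in the retina (482 ± 86.6 against 35.6 ± 28.5 CPM, adjusted p = 1.89e-05) and TMEM119 14.1-fold. CX3CR1 was 4.40-fold higher there (adjusted p = 0.0265), but did not pass without choroid replicate 3 (0.0655) or 10 (0.0596). Without 1 choroid replicate the folds of CD209 (log2 6.07 without replicate 3) and SIGLEC1 (4.72 without 8) shrank by over 1.5 times and stayed called.

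Of 14 genes of lipid-associated phagocytes 2 rose and 6 fell in the choroid (5 and 6 over the list alone), with the apolipoprotein genes APOE and APOC1 12.1- and 23.4-fold higher in the retina. Glycolysis genes were lower in choroidal phagocytes, 15 of 21 (16 over the list alone), such as HK2, 10.5-fold higher in the retina. Of 21 interferon response genes 8 rose in the choroid (11 over the list alone), among them IFITM3 (3.91-fold, log2 fold 1.97, and 1.19 without choroid replicate 3) and MX2 (3.95-fold). These 5 lists passed camera with the preset correlation (adjusted p = 6.32e-14 for tissue macrophage, 6.42e-06 for homeostatic microglia, 0.00402 for lipid-associated, 2.68e-10 for glycolysis and 0.000121 for interferon genes). None passed with an estimated one (adjusted p = 0.0738, 0.104, 0.329, 0.104 and 0.329 with an estimated correlation), except tissue macrophage genes with specimen as a block (10 of 10 rose, adjusted p = 0.0303 with an estimated correlation). Beside them, 17 of 18 rod phototransduction genes were lower in choroidal phagocytes, all free RNA by the rule, such as RCVRN (log2 fold −7.85).

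Of the 1987 genes, 952 were higher in the choroid and 1035 in the retina, and 1377 lay above the free-RNA rule. The blocked fit over 4 pairs called 1213, 611 and 602, of which 972 were shared. Replicates 1 to 4 alone called 378 and replicates 6 to 12 alone 1893, with 1753 of 1757 and 1984 of 1985 pooled calls in the same direction. Retinal phagocytes lay in clusters 19 and 40 and choroidal ones in clusters 26 and 53, of which 53 was led by the monocyte genes S100A8 and S100A9.

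Endothelial-like cells of the 2 tissues differed in 711 of 6868 genes. MFSD2A (ENSG00000168389, chromosome 1, 39955112 to 39969968, plus strand), the lipid transporter of barrier vessels, stood at 244 ± 181 CPM in the retina and 3.22 ± 4.997 CPM in the choroid (SD, n = 5 and 5). Its log2 fold was −7.33 ± 0.73 (edgeR adjusted p = 2.31e-05). SRARP (ENSG00000183888, chromosome 1, 16004236 to 16008807, plus strand) stood at 841 ± 191 and 3.32 ± 3.14 CPM (adjusted p = 4.63e-07). Of 12 blood-retina barrier genes 9 were lower in the choroid and 0 higher (10 and 0 over the list alone), such as the amino acid transporter gene SLC7A5 (80.8-fold), the glucose transporter gene SLC2A1 (9.86-fold) and the tight junction gene CLDN5 (7.15-fold). The list passed camera (adjusted p = 4.73e-16, and adjusted p = 0.00959 with an estimated correlation) but not with an estimated correlation and specimen as a block over 2 pairs (adjusted p = 0.673). Choroidal endothelium held more PKHD1L1 (ENSG00000205038, chromosome 8, 109362477 to 109530330, plus strand), 68.0-fold, and more of the homeobox gene SIX3, 52.1-fold (525.5 ± 236 against 11.01 ± 13.4 CPM, adjusted p = 0.000138). It also held more PLVAP, which forms the diaphragms of fenestrated vessels, 21.5-fold (adjusted p = 0.000624, log2 fold 4.42, and 2.86 in the blocked fit). CA4 was 16.1-fold higher in the choroid (adjusted p = 0.0243) but not called without choroid replicate 4 (log2 fold 1.95, adjusted p = 0.0691). Without 1 choroid replicate the folds of PLVAP (log2 3.52 without replicate 4) and PKHD1L1 (5.48 without 8) shrank by over 1.5 times and stayed called.

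Vein genes rose in choroidal endothelium, 4 of 7 (6 over the list alone), such as the adhesion genes VCAM1 (28.1-fold) and SELP (39.98-fold; camera adjusted p = 1.94e-07, adjusted p = 0.0438 with an estimated correlation, and adjusted p = 0.673 with that and the block). The retinal level of SELP rests on replicate 11 (21.1 CPM, the others at 0 to 2.19 CPM). Its fold grew without the barcodes shared in that replicate. Artery genes rose too, 6 of 9 (7 over the list alone), such as GJA5 (27.4-fold; camera adjusted p = 6.73e-05, but adjusted p = 0.286 with an estimated correlation). Inflammatory genes rose 7 of 12 (8 over the list alone; camera adjusted p = 0.000484, but adjusted p = 0.302 with an estimated correlation). Of 19 glycolysis genes 8 fell (13 over the list alone; camera adjusted p = 1.94e-07, adjusted p = 0.0438 with an estimated correlation, and adjusted p = 0.673 with that and the block). MHC class II genes rose 5 of 7 (5 over the list alone), among them HLA-DRA (6.97-fold) and CD74 (4.25-fold; camera adjusted p = 8.15e-06, but adjusted p = 0.14 with an estimated correlation). Of the 7 measured genes, 2 lay above the free-RNA rule. HLA-DRA stood at 296 to 885 CPM in the choroidal endothelial sums. In choroidal phagocyte-like cells it averaged 4326 CPM in the macula and 6041 CPM in the periphery. Free RNA as a source of its rise was not tested. Rod phototransduction genes, all free RNA, fell 9 of 10 (10 over the list alone) with a median log2 fold of −6.13. Of the 711 genes, 356 were higher in the choroid and 355 in the retina, and 631 lay above the free-RNA rule. The blocked fit over 2 pairs called 1297, 622 and 675, of which 515 were shared. Retinal sums came from replicates 6 to 12, which alone called 956 with 711 of 711 in the same direction, and cluster 39 held the class in both tissues.

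**Figure D4:**
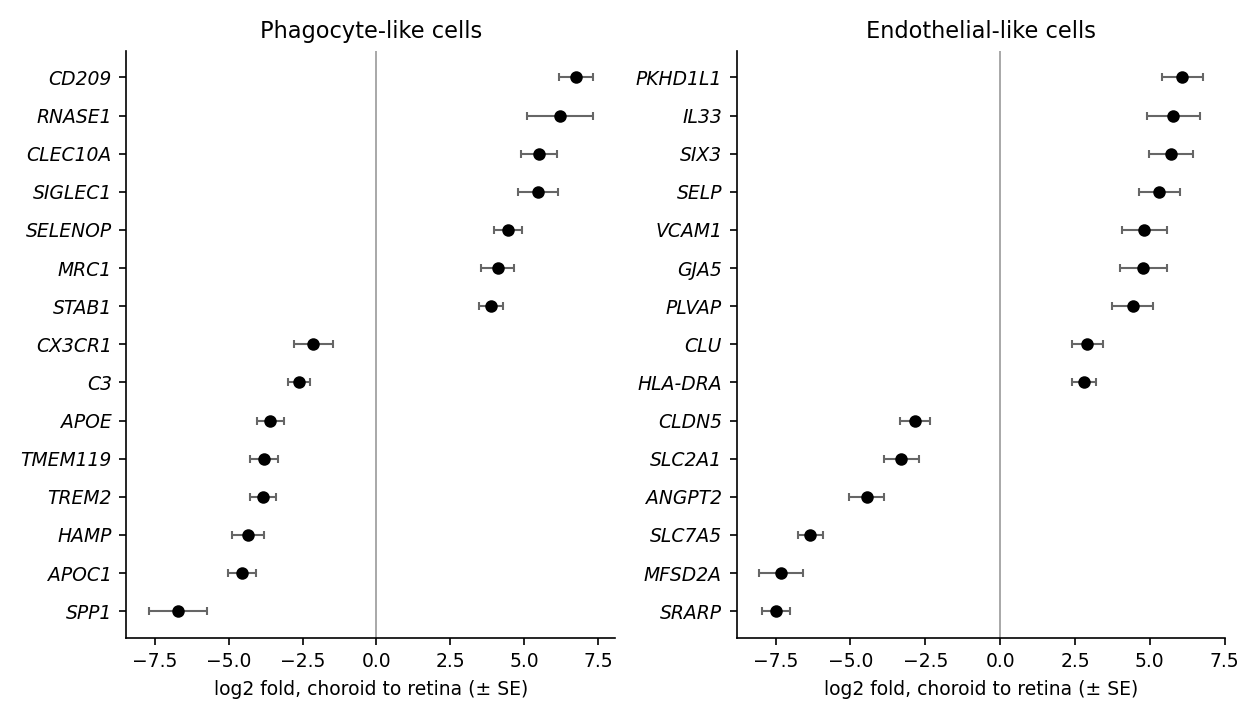
Log2 fold change, choroid to retina (x axis), of named genes (y axis) in phagocyte-like cells (5 choroid and 10 retina specimens) and endothelial-like cells (5 and 5); points are fitted values and bars are ± 1 SE. CD209 stood at 6.75 and SPP1 at −6.72 in phagocytes, and PKHD1L1 at 6.09 and SRARP at −7.48 in endothelium.

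Whether the regional difference of phagocyte-like cells itself differed between tissues was tested on 8 macular and 9 peripheral sums of replicates 1, 3, 4, 8 and 10. All 4 sums were at hand for replicates 3, 8 and 10 alone. The edgeR interaction test called 0 of 9500 genes (69 at an unadjusted p under 0.05, 0 by DESeq2), and 0 in each batch. The blocked fit called 2, RGR (log2 −3.58 ± 0.48, adjusted p = 0.00834), a gene of the pigment epithelium, and PCP4 (−4.16 ± 0.65, adjusted p = 0.0266), both below the free-RNA rule and named after their values were seen.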

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

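The tests of rods among the barcodes taken out, of the processing batch, of the RNA quality of whole libraries and of free RNA in bipolar-like cells were chosen after the results they bear on were seen.

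Rod-like cells were nearly missing from retina replicates 2 to 4, at 0 of 6687 macular and 0 of 5630 peripheral cells in replicate 2 (which allow shares of up to 0.0449% and 0.0533%), 5 of 10013 and 5 of 7518 in replicate 3, and 7 of 8005 and 23 of 5480 in replicate 4 (0.420%, exact Clopper-Pearson 95% interval 0.266 to 0.629). Rods and barcodes taken out at rod level made up at most 0.244% of barcodes there, against a lowest rod share of 8.33% of barcodes in replicates 6 to 12, which argues against the filters, while a looser bound, 19.8% of barcodes that were rods or were taken out for any reason, could not decide. Rod-list UMIs in bipolar-like cells reached 0.0503% of UMIs in these libraries, below the lowest of replicates 6 to 12 (0.0623%). The gap is small, and replicate 2, with 0 rods, held 0.0317% in the macula and 0.0467% in the periphery. The measure cannot tell free rod RNA from the cells' own UMIs. It therefore does not decide whether rods broke open and left their RNA in the droplets. Replicate 1, of the same processing batch, held 14.2% rods in the periphery and 7.26% in the macula, so rods were not nearly missing throughout that batch. The lowest share of replicates 6 to 12, 11.8%, was that of a macular library. Within its own region each library of replicate 1 lay below all later ones (means of 45.9% in the periphery and 26.4% in the macula). A part of the batch in the loss stays open, and replicate 1 is 1 specimen. Loss of whole rods before loading and a difference between specimens were not tested and stay open.

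The 13 mitochondrially encoded genes were lower in macular Müller-like cells, with a median log2 fold of −1.29. In bipolar-like cells of the same libraries the list's median averaged 0.0957 ± 0.0541 (SE, n = 11), against −1.14 in Müller-like cells. The Müller-like value was the lower in 11 of 11 specimens (exact sign-flip p = 0.000977). That argues against a lower RNA quality of the macular libraries as a whole, with bipolar-like cells as the 1 class compared. A part of free RNA was not tested, and the rod list, free RNA here, also had a negative median log2 fold in Müller-like cells. With log2 UMIs per cell as a covariate the median was −1.25, and among cells with at least 500 genes and at most 10% mitochondrial UMIs it was −1.16, each with 13 of 13 genes called by edgeR, which excludes both as the whole cause. A loss of these transcripts from macular Müller glia alone during dissociation was not tested. A regional difference of Müller glia stays a hypothesis, found and tested on the same data.

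The 8 named genes higher in macular bipolar-like cells had a median log2 fold that averaged 0.89 over 11 specimens. With each specimen's bipolar clusters weighted alike in both regions it averaged 0.25 ± 0.04 (SE) and was above 0 in 10 specimens. Clusters with under 10 cells in either library of a specimen were left out of the weighting. The clusters were built from the expression of the same cells, so a regional difference within a bipolar type could itself part clusters. The fall therefore cannot tell a different mix of bipolar types from a difference within a type. HR kept a log2 fold of 1.41 with that weighting, while RELN went from 1.36 to 0.46, KCNA1 from 1.30 to 0.25 and HS3ST4 from 0.89 to −0.09. A test of free RNA from other cell types gave 0 of 8 genes and decides nothing, since the naming rule leaves such genes out. Whether the mix of clusters differs between regions through biology or sampling was not tested.

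Of 209 groups of 4 to 10 samples, 34 held a sample far from the others, where chance gives about 1 in 20, or 10.45. Among class shares of the choroid, macula choroid replicate 10 held 0.520% Müller-like cells (exact 95% interval 0.326 to 0.786) and 2.27% pigment epithelium-like cells (1.84 to 2.76), and peripheral choroid replicate 10 held 19.1% pigment epithelium-like cells (18.2 to 19.9). Schwann-like cells stood at 25.5% (24.0 to 27.1) in macula choroid replicate 4 and 16.3% (15.2 to 17.5) in peripheral choroid replicate 4. Fibroblast-like cells stood at 40.5% (38.6 to 42.4) in macula choroid replicate 1 and 75.1% (73.1 to 77.0) in peripheral choroid replicate 1, and rod-like cells at 0.747% (0.457 to 1.15) in macula choroid replicate 1.

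The others were log2 CPM values with a prior count of 2. In choroidal endothelial-like cells CRHBP was lowest in macula choroid replicate 10 (3.46), and CYP1B1 (3.34) in macula choroid replicate 4. In fibroblast-like cells CFD was lowest in macula choroid (3.51) and peripheral choroid (4.06) replicate 1, and SFRP4 (2.81) and SMOC2 (5.88) in peripheral choroid replicate 10. CCND1 of melanocyte-like cells was lowest in macula choroid replicate 4 (−1.40). RGR of phagocyte-like cells was highest in macula choroid (4.18) and peripheral choroid (6.99) replicate 10, the specimen with the most pigment epithelium-like cells, CPVL was lowest in peripheral retina replicate 10 (4.02), and LYVE1 was highest in macula retina replicate 11 (7.36). In rod-like cells of the shallow replicate 1, CEP170B was highest (7.85) and COX4I1 (6.45) and PRL (−1.76) lowest in the macula, and COX4I1 (6.90) and RPL4 (6.75) lowest in the periphery. In peripheral retina replicate 4, GNGT1 (9.66), SAG (10.86) and PRL (−1.76) were lowest. With both regions added, endothelial CA4 (10.34) and PLVAP (9.60) were highest in choroid replicate 4, and phagocyte CLEC10A (3.41), HAMP (3.65), RNASE1 (6.52) and SELENOP (7.73) were lowest in choroid replicate 1.

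The regional difference of phagocyte-like cells differed between tissues for 3 gene lists by camera on the interaction, heat shock (median log2 difference −1.14, adjusted p = 0.000821), ribosomal proteins (−0.32, adjusted p = 0.00246) and nuclear oxidative phosphorylation genes (−0.26, adjusted p = 0.00654). With an estimated correlation none of the 3 passed (adjusted p = 0.958 for each), and edgeR called 0 of their genes (69 of all genes at an unadjusted p under 0.05, 0 by DESeq2).

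The library of pooled, hashed tissues, in no group, held 12732 cells, in which a class needs more than 0.0236% to pass the limit that a count of 0 allows. Natural killer and T cell-like cells made up 34.2% (exact 95% interval 33.3 to 35.0), bipolar-like 31.6% (30.8 to 32.4), fibroblast-like 12.1% (11.6 to 12.7) and Müller-like cells 11.5% (10.9 to 12.02). Melanocyte-like cells made up 2.66% (2.39 to 2.96), phagocyte-like 2.36% (2.10 to 2.63), B and plasma cell-like 2.20% (1.95 to 2.47), Schwann-like 1.43% (1.23 to 1.65) and unnamed cells 1.01% (0.839 to 1.19). Astrocyte-like cells made up 0.346% (0.251 to 0.464), erythrocyte-like 0.196% (0.127 to 0.290), rod-like 0.110% (0.0601 to 0.184) and endothelial-like cells 0.102% (0.0544 to 0.175). Horizontal-like cells made up 0.0864% (0.0431 to 0.155), cone-like 0.0550% (0.0221 to 0.113), amacrine-like 0.0471% (0.0173 to 0.103) and mural-like cells 0.0393% (0.0128 to 0.0916).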

How the results depend on the processing

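Leaving out retina replicate 7 and leaving out the barcodes shared in replicate 11 were chosen after the data were seen. Of 202 recomputed counts of called genes and classes, 152 stayed within 1.5 times of the reported count and 50 did not. A count of 0 that stayed 0 was taken as within 1.5 times. The reported count was 0 for retinal phagocytes, choroidal endothelium, melanocytes, choroidal phagocytes, the interaction and the choroid shares. The 152 therefore overstate how stable the calls are. Of the recomputed values of 86 named genes called in the reported tests, 1120 kept direction and call, 54 kept direction alone and 0 changed direction, and of those of 18 called class shares 184, 40 and 1. The cause of the shifts below was not tested, except that dropping cells, sums or genes leaves fewer of them to test.

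With specimen as a block, edgeR called 476 genes in rods, 141 in cones, 1570 in bipolar cells, 6489 in Müller glia, 56 in retinal phagocytes, 36 in choroidal endothelium, 404 in fibroblasts, 259 in melanocytes, 4 in choroidal phagocytes, 1213 in phagocytes and 1297 in endothelium between tissues, and 2 for the interaction. With specimens paired, 0 of 18 class shares differed between tissues, where 5 pairs cannot give an exact p below 0.0625. Of the unblocked calls the block kept 36 of 43 in cones, 1656 of 1657 in Müller glia, 972 of 1987 in phagocytes and 515 of 711 in endothelium between tissues, and all in rods, bipolar cells and fibroblasts.

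Without the filter on low counts edgeR called 28 genes in rods, 79 in cones, 10 in fibroblasts, 3102 in phagocytes and 1560 in endothelium between tissues. DESeq2 called 29 in rods, 92 in cones, 147 in bipolar cells, 2763 in Müller glia (1055 higher in the macula and 1708 lower), 4 in retinal phagocytes, 33 in fibroblasts, 3342 in phagocytes and 1458 in endothelium between tissues. Cells with at least 500 genes and at most 10% mitochondrial UMIs gave 18 in rods, 10 in bipolar cells and 1 in fibroblasts, and sums of at least 50 cells 5 in rods and 15 in cones. Leaving out free RNA gave 0 in rods (160 at an unadjusted p under 0.05), 25 in cones, 12 in bipolar cells, 1003 in Müller glia and 2 in melanocytes. Keeping doublets gave 1 in melanocytes and 1224 in endothelium between tissues, finer clusters gave 0 in fibroblasts (205 at an unadjusted p under 0.05), and leaving out the shallow libraries 17 in rods and 3173 in Müller glia. RLE normalization moved no count by over 1.5 times, and under TMM, RLE and DESeq2's scaling the median log2 fold of the genes tested stayed within 0.1 of 0.

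Leaving out each choroid replicate gave 0 to 7 genes in fibroblasts and 0 to 3 in melanocytes. Without retina replicate 7, 28 genes were called in cones and 1 of 15 class shares differed in the retina. Without the shared barcodes 43 genes were called in cones, as with them. These barcodes, 5.65% of the cells of macula retina replicate 11 and shared with peripheral retina replicate 11 (next highest of 528 pairs of libraries 0.626%, median 0.256%), moved no count by over 1.5 times, but endothelial SELP between tissues went from a log2 fold of 5.32 to 7.65 without them. Among cells that are not rods 1 class of the retina differed in share. The share of mural-like cells, lower in the choroid, was higher there with finer clusters, by 5.31 percentage points (exact permutation, adjusted p = 0.00177).

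TBX15 was lost without any 1 choroid replicate, and TFPI2 without replicate 3, 4 or 8 and with finer clusters. RPE65 in cones was lost with RLE (adjusted p = 0.0515) and DESeq2 (0.16), CA4 between tissues with sums of at least 50 cells (0.108), and CX3CR1 between tissues among the stricter cells (0.0752). No test of ganglion-like cells was run under any alternative, since no peripheral library held 20. In simulations 27.9% of 68 unblocked calls in melanocytes and 10.8% of 167 blocked calls in rods were false.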

Other observations

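All tests of other splits of the samples in the last paragraph were chosen after the results were seen.

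Macular Müller-like cells also held more RAB3B, a small GTPase of vesicle release, 13.5-fold (70.2 ± 36.5 against 5.50 ± 3.05 CPM, SD, n = 11 and 11, log2 fold 3.76 ± 0.35, edgeR adjusted p = 1.42e-07). The tetraspanin gene CD9 was 2.63-fold and RDH11, a retinol dehydrogenase, 1.64-fold higher in the macula (edgeR adjusted p = 0.00709 and 0.00981). The desmosome gene DSP was 15.3-fold higher in the periphery (67.2 ± 42.5 against 4.65 ± 3.58 CPM, adjusted p = 5.15e-06). So were the noncoding RNA DIO3OS, a neighbour of DIO3, 12.8-fold (adjusted p = 2.97e-05), and the growth factor gene HBEGF, 8.04-fold (adjusted p = 0.00537). Choroidal phagocyte-like cells held more RNASE1, a secreted ribonuclease, 74.1-fold (log2 fold 6.21 ± 1.11, n = 5 and 10 specimens). They also held more CLEC10A, a lectin of dendritic cells and macrophages, 45.4-fold (5.50 ± 0.59), and the matrix glycoprotein gene THBS1, 5.50 ± 0.82 on the log2 scale. Retinal phagocyte-like cells held more HAMP, the iron-regulating hormone hepcidin, 20.2-fold (1428 ± 914 against 72.8 ± 36.5 CPM, edgeR adjusted p = 2.78e-05), and the complement gene C3, 6.15-fold. Of 10 measured loci tied to age-related macular degeneration, 2 rose and 5 fell in choroidal phagocytes (4 and 5 adjusted over the list alone; camera adjusted p = 0.0266, but adjusted p = 0.104 with an estimated correlation).

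In endothelial-like cells ANGPT2, an antagonist of TIE2 signalling, was 21.9-fold higher in the retina (1555 ± 377 against 66.3 ± 56.3 CPM, SD, n = 5 and 5, edgeR adjusted p = 0.000168). IL33 was 55.1-fold (130.3 ± 136 against 2.93 ± 4.14 CPM, from 2252 against 8 UMIs, log2 fold 5.78, and 5.03 without choroid replicate 10) and CLU, the chaperone clusterin, 7.48-fold higher in the choroid. Of 11 collagen and matrix genes 4 rose and 0 fell in the choroid (7 and 1 over the list alone; camera adjusted p = 0.00149, but adjusted p = 0.14 with an estimated correlation). Of 8 retinoic acid and thyroid hormone genes 4 rose and 0 fell (5 and 0 over the list alone; camera adjusted p = 0.0036, but adjusted p = 0.0509 with an estimated correlation). Of 5 metallothionein genes 0 rose and 3 fell (0 and 4 over the list alone; camera adjusted p = 0.0205, but adjusted p = 0.491 with an estimated correlation). Cluster 30 held 2375 cells, doublet-scored ones included, 98.8% of them from macula choroid replicate 8, and was led by CCL23, FOLR2, SIGLEC1, STAB1 and VWF, genes of macrophages and of endothelium, so it stayed unnamed.

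Other splits of the samples exclude chance for Müller glia (1 of 100 splits as large, the real one included; 1657 genes against 26 in the highest other), bipolar cells (1 of 100; 57 against 25) and cones (1 of 100; 43 against 3). They also exclude it for phagocytes between tissues (1 of 100; 1987 against 4) and endothelium between tissues (1 of 100; 711 against 3). For rods (2 of 100; 9 against 67) another split called far more genes than the real one, and all 9 genes lay below the free-RNA rule. These splits therefore do not exclude chance for rods. Among splits that part all 8 pairs of rod sums, 1 of 100 was as large, the real one included. For fibroblasts (2 of 100; 2 against 41) splits that ignore the pairs do not exclude chance either. Those that part all 5 pairs number 16, too few for a share under 0.05. For both classes 1 other split called several times the real count, which points to a structure of the samples. That of rods put the 3 sums of replicates 1 to 4 on 1 side, beside 6 later ones, against 8 later ones. That of fibroblasts lay close to the batch, with 5 sums of replicates 1 to 4 against 1 of them and 4 later ones. Within a batch fibroblasts gave 0 calls, and 404 with the block. Where 0 genes were called every split is as large whatever the data, so the count decides nothing about chance. The highest other split called 8 in retinal phagocytes, 326 in choroidal endothelium, 337 in melanocytes, 59 in choroidal phagocytes and 142 for the interaction. In choroidal endothelium and melanocytes the highest split was exactly that of replicates 1 to 4 against 8 and 10, and in choroidal phagocytes close to it. The blocked fits called 36, 259 and 4 genes there and each batch alone 0. Among splits that part as many pairs of a specimen as the real one, the highest other called 3 in rods, 1 in cones, 0 in bipolar cells, Müller glia and fibroblasts and 220 in phagocytes between tissues (16 such splits, too few for a share under 0.05). In endothelium between tissues 32 of the 100 splits did so, and the highest other called 1.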
